A study of Danio rerio with 10 samples.

How the data were processed

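Gene expression was measured by RNA sequencing of 10 libraries from whole wild-type zebrafish embryos exposed to thallium nitrate at 0 ppb (5 libraries), 200 ppb (3) and 800 ppb (2) from 6 to 48 hours post fertilisation. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, replicate 1 of 0 and of 200 ppb was prepared at a hospital sequencing core and the other 8 libraries by a commercial provider. The submitters' processing notes name FastQC, cutadapt, STAR and edgeR without versions or roles, and the build GRCz11; the counter, the annotation release and the strand setting are not given in the sources used here. Genes that overlap on opposite strands could therefore not be told apart.

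The authors deposited whole-number read counts per Ensembl gene for each library, and these counts were the input of the main test. The files of the hospital core held 463 further features, 0.339% and 0.342% of their counts, and the 32057 genes shared by all 10 files were used. The authors also deposited a series table of 18963 genes, named as CPM, whose values are on a log2 scale: undoing the logarithm with a prior count of 2 gave whole reads for 100% of the values tested, within a tolerance of 0.05 reads. Those reads equalled the count files for the hospital core's 2 libraries and came from another count set for the provider's 8, with totals 1.12 to 1.19 times as large. An alternative planned on log2(CPM + 1) was therefore run on the deposited log2 values without a further logarithm, and the recovered reads were tested as an added alternative.

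Symbols came from a table of gene IDs, which named 28988 of the 32057 genes; it uses human-style symbols where a single zebrafish gene has a human match, and 2 genes carry the symbol HSPA8, told apart here by ID. Of 1350 entries in 48 gene lists, 971 matched by the same symbol, 64 after dropping a paralog letter and 315 not at all. The lists, of pathways and of markers for cell types of a whole embryo, were written before the data were examined, as were the design, the alternatives marked as planned and the rule for named genes. By that rule the text names, per comparison, up to 8 rises and 8 falls past the threshold with a proper symbol, a mean of at least 1 CPM and separation from each site-matched library, up to 4 members with the smallest p of each called list, and the 5 genes with the smallest p where fewer than 5 passed. The list of ribosomal proteins was defined by a name pattern that also took in a few kinases such as rps6kb1b. No genome was used, and no coordinates are given. Of the genes checked for a library far apart, 1 is not reported here.

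Counts were fitted with edgeR 4.0.16 in R 4.3.3 over all 10 libraries, with TMM scaling, filterByExpr by dose group, the site of library construction and the dose as terms, and the quasi-likelihood F-test (two-sided). A gene changed when its Benjamini-Hochberg adjusted p was under 0.05 among the 20867 genes tested, of which 19983 had a symbol. The 800 ppb group, with 2 libraries, drew its spread from all groups. Depth ran from 12.1 to 48.3 megareads per library, and the median standard error of a log2 fold change was 0.203 for 200 ppb against 0 ppb with the site term and 0.138 with the batch term, and 0.24 and 0.185 for 800 ppb against 0 ppb. CPM values use TMM-scaled totals, and fold changes are from the fit. Gene lists with at least 5 measured members were tested with camera in limma 3.58.1 on voom values of the same design, with a preset correlation of 0.01, and again with the correlation estimated and with fry, adjusted over the 48 lists of each comparison. With the correlation estimated, camera also uses only the residual degrees of freedom of the fit. A list can therefore lose its call in that setting without correlated members. Counts per list are given over all genes and adjusted over the list alone. DESeq2 1.42.0 and limma-voom were alternative tests. Tables were prepared with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.

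Library batches were derived from the data. For 13296 genes with at least 50 reads, the log ratio of the count files to the reads recovered from the series table was correlated between the provider's 8 libraries. Correlations were 0.919 to 0.960 within 3 clusters and 0.789 to 0.851 between them, and with the hospital core's libraries this gave 4 batches. The number of 3 clusters was set and not estimated. The ratio compares both count sets of the same libraries and does not use the dose, but what makes it differ between libraries was not tested. Fits with the batch in place of the site term were added after the data were seen; their common dispersion was 0.00757 with 4 residual degrees of freedom, against 0.0419 with 6 for the site term.

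Same-numbered libraries were compared by the correlation of their deviations from the group mean. It was 0.893, 0.511 and 0.685 for replicates 1, 2 and 3 of 0 and 200 ppb, so the numbers pair these groups. Replicates 1, 2 and 3 of both doses are also batches 1, 2 and 3, so paired samples cannot be told apart from a shared batch. For 800 ppb it was -0.141 and 0.0385 against 0 ppb and -0.113 and -0.0595 against 200 ppb. With 2 libraries in that group their deviations mirror each other, so this measure can hardly show or exclude pairs there. The same-numbered libraries of 800 ppb lie in another batch, and the numbers were not taken as pairs. With the replicate block and the site term the 200 ppb comparison called 6 genes. No libraries of the same group were copies of each other: the chi-square per degree of freedom between libraries of a group was 5.89 to 179.

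Alternatives covered the site term, the libraries in the fit, 3 other scalings, the filter on low counts, robust dispersion, stricter thresholds, the deposited log2 table, replicate blocks and each library left out in turn. The relation between both dose effects was set beside 20 simulations of unchanged groups that share the 0 ppb libraries. In a test on simulated data, with 200 of 20867 genes changed in each of 5 simulations, the fit with the site term at 800 ppb recovered 0.597%, 29.0% and 74.8% of genes changed by 0.5, 1 and 2 on the log2 scale with 0% false calls, and the fit with the batch term 29.6%, 72.8% and 95.8% with 7.57% false calls. At 200 ppb the recoveries were 2.09%, 44.2% and 86.7% with the site term and 49.0%, 86.0% and 99.1% with the batch term, with 0% and 7.92% false calls. The simulated counts were drawn from the model with the batch term, which favours that fit, so these recoveries cannot rank both terms. The simulations held no further grouping of libraries inside a batch, so the share of false calls in the real data may be higher.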

Results

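The series measured gene expression in whole wild-type zebrafish embryos that had been kept in thallium nitrate between 6 and 48 hours post fertilisation. Thallium is a toxic heavy metal whose monovalent ion resembles potassium. Libraries were made from 5 samples at 0 ppb, 3 at 200 ppb and 2 at 800 ppb, and each gave a count of reads per gene over 32057 genes. Total counts, in megareads, were 48.3 at 0 ppb in replicate 1, 16.5 in replicate 2, 15.6 in replicate 3, 12.3 in replicate 4 and 13.6 in replicate 5. At 200 ppb they were 32.2, 16.6 and 15.6 in replicates 1 to 3, and at 800 ppb 14.9 and 12.1 in replicates 1 and 2. The labels do not say whether replicates came from separate clutches, so p-values measure the spread between these samples, which may be technical.

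The libraries were placed in 4 batches, defined from the ratio of both deposited count sets and not from the dose. Batch 1 held replicate 1 of 0 and 200 ppb, built at a hospital core. The other 8 libraries came from a commercial provider: replicate 2 of 0 and 200 ppb formed batch 2, replicate 3 of both formed batch 3, and 0 ppb replicates 4 and 5 formed batch 4 with both 800 ppb libraries. For 10 of the 10 libraries the most similar other library was in the same batch, with a correlation across genes of 0.981 to 0.996. Transcripts of the mitochondrial genome took 2.41% to 2.44% of counts in batch 1, 1.94% to 1.97% in batch 2, 3.81% to 3.83% in batch 3 and 4.25% to 4.61% in batch 4.

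**Figure D1:**
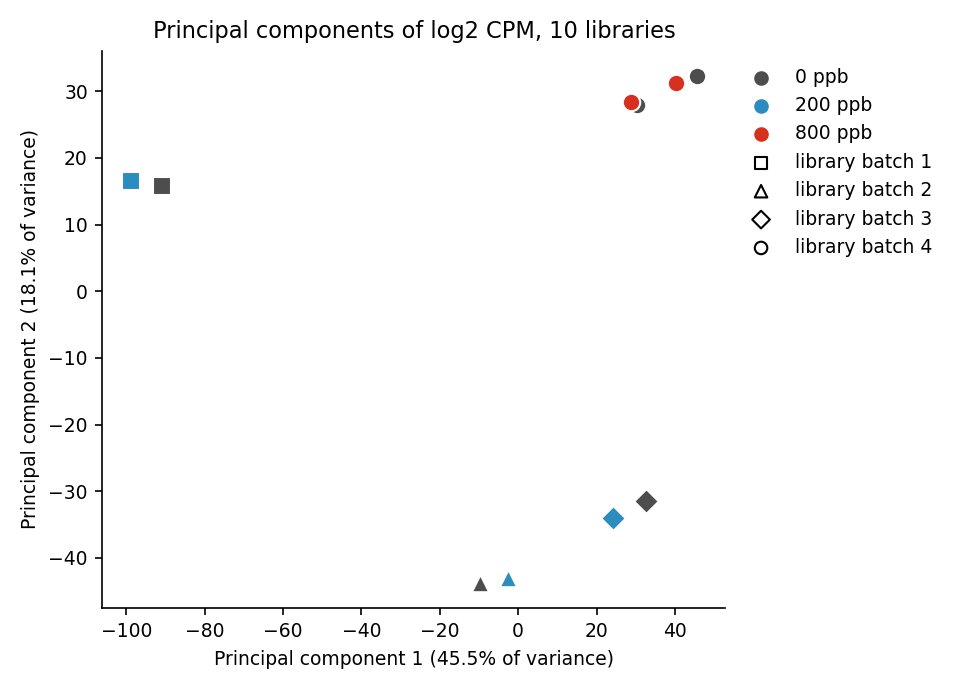
Scores of the 10 libraries on the first and second principal components of log2 CPM, with 45.5% and 18.1% of the variance; each point is a library, colours give the dose and shapes the library batch. Libraries of the same batch lie together whatever their dose.

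The comparison of 800 ppb with 0 ppb asked which transcripts differed in embryos at the highest dose. Embryos at 800 ppb held more transcripts of 4 heat shock chaperone genes, of the amino acid transporters SLC1A4 and SLC7A3 and of asparagine synthetase. HSP90AA1 (ENSDARG00000024746), a chaperone that helps client proteins fold, rose 3.62-fold (log2 fold change 1.86, SE 0.18), from 90.7 ± 23.9 CPM (SD, n = 5) to 359 ± 66.0 CPM (SD, n = 2). From the HSP70 chaperone family, hsp70.3 rose 5.22-fold (log2 fold change 2.39, SE 0.34), hsp70l 3.69-fold (1.88, SE 0.26) and the HSPA8 gene ENSDARG00000037403 3.55-fold (1.83, SE 0.23). The neutral amino acid transporter SLC1A4 rose 2.36-fold (log2 fold change 1.24, SE 0.17), the cationic amino acid transporter SLC7A3 1.94-fold (0.96, SE 0.12) and asparagine synthetase, ASNS, 2.05-fold (1.04, SE 0.14).

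EPAS1, a transcription factor of the hypoxia response, rose 2.04-fold, from 113 ± 9.63 CPM (SD, n = 5) to 224 ± 46.7 CPM (SD, n = 2). The apolipoprotein gene apoa4a fell by 1.16 on the log2 scale (SE 0.15), from 30.6 ± 8.21 CPM (SD, n = 5) to 15.2 ± 1.13 CPM (SD, n = 2). These 9 genes, 8 higher and 1 lower, were all that passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment among 20867 genes, with a term for the site of library construction. Their adjusted p ran from 0.00891 for HSP90AA1 to 0.0483 for hsp70.3. An unadjusted p under 0.05 was found for 993 genes, no more than the share of 0.05 expected without any change. When the 0 and 800 ppb libraries were regrouped in 21 ways, 8 groupings, the real one among them, gave as many. In each of the 9, both 800 ppb libraries lay beyond each of the provider's 4 libraries at 0 ppb.

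The call of 9 genes rested on small margins: leaving out 0 ppb replicate 4 or 5 or 800 ppb replicate 1 left 0 genes, leaving out 0 ppb replicate 1 or 3 or any of the 200 ppb libraries left 1. The tool limma-voom called 2 genes and DESeq2 42. In each of these fits the 9 genes kept their direction, and 9 of 9 were among those DESeq2 called. The fits share nearly all libraries with the one that chose these genes, so the direction could hardly change. Reads from near-identical copies can be split between hsp70.3, hsp70l and their neighbours, and between the HSP90 genes, so the level of each copy is uncertain. The totals of these families were not tested.

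**Figure D2:**
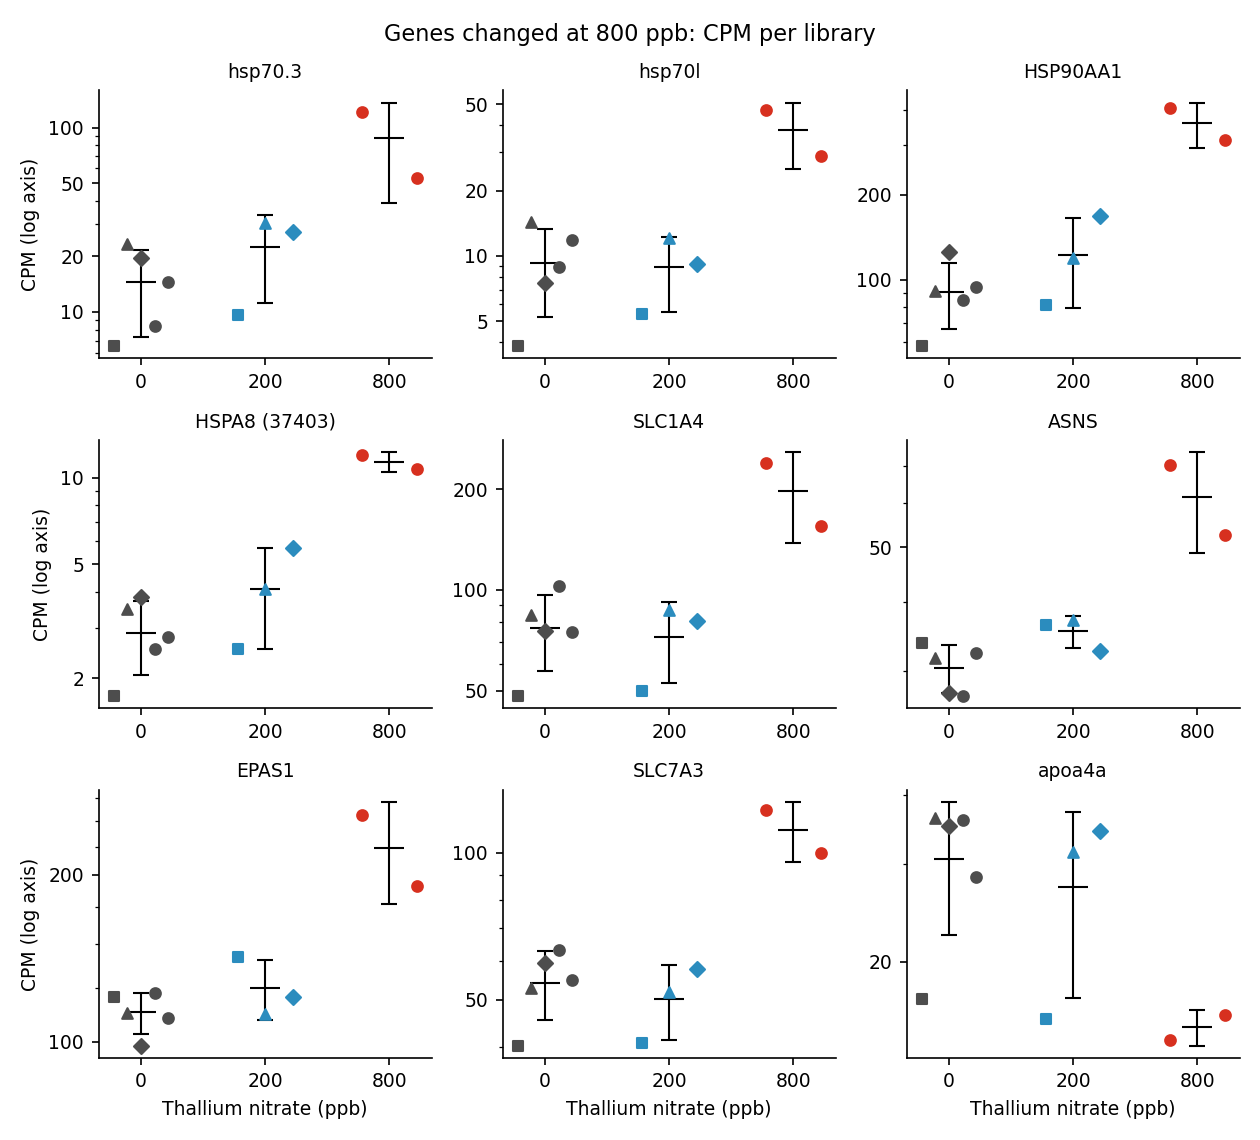
CPM on a log axis against the thallium nitrate concentration in ppb for the 9 genes changed at 800 ppb; points are libraries, shapes give the library batch (square 1, triangle 2, diamond 3, circle 4), and bars show the mean ± SD of 5, 3 and 2 libraries. HSP90AA1 averages 90.7 CPM at 0 ppb, 123 CPM at 200 ppb and 359 CPM at 800 ppb.

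Within batch 4, the only batch that holds 800 ppb libraries, 2 libraries at each dose could be set side by side. With the library batch as a term, an alternative chosen after the data were seen, 65 genes changed, 49 higher and 16 lower, and these held 9 of the 9 named above with the same sign. MT1X, a metallothionein that binds metal ions, rose 3.73-fold (log2 fold change 1.90, SE 0.18), from a mean of 23.1 CPM in the 2 libraries at 0 ppb of that batch to 85.7 ± 16.7 CPM (SD, n = 2), with an adjusted p of 0.000128 by edgeR with Benjamini-Hochberg adjustment. HSPA2, another HSP70 gene, rose 4.39-fold (2.13, SE 0.32), adm2a, which encodes an adrenomedullin-type peptide, rose by 2.04 on the log2 scale (SE 0.36), and mdp1 rose 3.39-fold (1.76, SE 0.29). The potassium channel gene KCNJ1 fell by 1.36 on the log2 scale (SE 0.27), SOAT2, which esterifies cholesterol, fell by 1.27 (SE 0.24), and ACP5, an acid phosphatase of bone-resorbing cells, fell by 1.06 (SE 0.19). Selenoprotein P, selenop, a carrier of selenium, fell by 0.76 (SE 0.07), from 1001 CPM to 590 ± 10.8 CPM (SD, n = 2), and pyruvate carboxylase, PC, fell by 0.76 (SE 0.09). afp4 fell by 0.61 (SE 0.09) and otos2 by 0.59 (SE 0.10), and 7 of the 16 genes that fell had no symbol or only a clone name.

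With the site term in place of the batch term MT1X had an adjusted p of 0.638 by edgeR with Benjamini-Hochberg adjustment, HSPA2 0.897, KCNJ1 0.592 and selenop 0.25. The count of 65 became 33 without 800 ppb replicate 1, 114 without 800 ppb replicate 2, and 41 without replicate 2 of 0 or of 200 ppb. With the libraries of batch 4 in another arrangement, 0 ppb replicate 4 with 800 ppb replicate 1 against 0 ppb replicate 5 with 800 ppb replicate 2, 439 genes differed, and with 5 pairs of libraries as a term 274 genes changed at 800 ppb against 0 ppb. The labels do not give the pairs inside batch 4, which were chosen from that arrangement after the data were seen.

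Gene lists written before the data were examined were tested with limma's camera at a preset correlation of 0.01, and 16 of 48 were called at 800 ppb, 6 higher and 10 lower. The heat shock list rose: 20 of its 23 measured members lay above 0 with a median log2 fold change of 0.30, and its adjusted p was 7.55e-13, or adjusted p = 0.00701 with an estimated correlation. It was the 1 list of the 16 that held with an estimated correlation. Adjusted over the list alone 9 members passed, 8 higher and 1 lower, against 3 over all genes. dnajb1b, a co-chaperone, had a log2 fold change of 0.84 (SE 0.18), and hspb9, named after its values were seen, was the lower member with -0.98 (SE 0.36). With the batch term the list kept its call, with a median of 0.34, adjusted p = 0.0215 with an estimated correlation, 6 members past the test over all genes and 15 adjusted over the list alone. The 0 ppb libraries of batch 4 differed from the provider's other 0 ppb libraries by a median of -0.00379 on the log2 scale over this list.

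Genes of endoplasmic reticulum stress and the integrated stress response were higher as a list, with 32 of 47 measured members above 0 and a camera adjusted p of 3.81e-08. That call did not hold at an adjusted p = 0.562 with an estimated correlation, or at adjusted p = 0.479 with an estimated correlation under the batch term. Adjusted over the list alone 12 members passed, each of them higher, and over all genes ASNS alone passed. PSAT1, of serine synthesis, had a log2 fold change of 1.05 (SE 0.18), the asparaginyl-tRNA synthetase NARS1 0.83 (SE 0.15) and the transcription factor atf5b 0.75 (SE 0.14). With the batch term 8 members rose over all genes, and adjusted over the list alone 17 were higher and 1 lower. Among those that rose were PHGDH, the entry enzyme of serine synthesis, by 2.01-fold (1.01, SE 0.12) and NARS1 by 1.77-fold (0.82, SE 0.11). HSPA5 and HSP90B1, chaperones of the endoplasmic reticulum named after their values were seen, had log2 fold changes of -0.07 (SE 0.15) and -0.04 (SE 0.12).

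The other 14 lists called at 800 ppb ended at adjusted p = 0.562 to 0.792 with an estimated correlation. Lens crystallins (35 of 43 members at or below 0, median log2 fold change -0.33), fast muscle (24 of 25, -0.23), nuclear-encoded respiratory chain genes (87 of 107, -0.15) and epidermis (30 of 38, -0.19) were lower as lists. None of the members of these 4 lists passed the test over all genes or adjusted over the list alone; the crystallin crygm2d20 had a log2 fold change of -0.63 (SE 0.19) and the muscle calcium pump gene atp2a1l -0.61 (SE 0.21). Beside them, the 0 ppb libraries of batch 4 were already lower than the provider's other 0 ppb libraries, by a median of -0.54 for lens crystallins, -0.31 for fast muscle, -0.23 for the nuclear respiratory chain and -0.20 for epidermis. Fast muscle stayed called lower with the batch term, 16 of 25 below 0 with a median of -0.05 (camera adjusted p 0.0359, adjusted p = 0.756 with an estimated correlation). The medians were then -0.04 for lens crystallins, -0.01 for the nuclear respiratory chain and -0.07 for epidermis, none of these 3 called.

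Respiratory chain genes of the mitochondrial genome were higher as a list, 12 of 13 with a median of 0.39, and the 0 ppb libraries of batch 4 lay 0.67 above the provider's other 0 ppb libraries. With the batch term the median was 0.12, and none of the 13 passed over all genes where 4 passed adjusted over the list alone (adjusted p = 0.479 with an estimated correlation). Lists of p53 targets (22 of 28 above 0), circadian clock genes (19 of 28) and NRF2 targets (15 of 27) were higher. Cartilage and bone (4 of 30 above 0), yolk syncytial layer and lipid genes (6 of 22), liver (11 of 37), inflammation (5 of 22) and ribosomal proteins (24 of 93) were lower. Over these 8 lists no member passed over all genes with the site term; adjusted over the list alone 1 p53 target was higher and 2 yolk syncytial and lipid genes were lower. Ribosomal proteins turned to higher with the batch term, 78 of 93 above 0 (camera adjusted p 1.54e-05, adjusted p = 0.79 with an estimated correlation). Circadian clock genes (camera adjusted p 0.0525), liver (0.101) and inflammation (0.113) were then no longer called. The p53 targets, NRF2 targets, cartilage and bone, and yolk syncytial and lipid genes stayed called, but none of them held with an estimated correlation.

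Thallium enters cells by potassium routes, and potassium channel genes were lower as a list at 800 ppb with the site term: 39 of 115 measured members lay above 0, with a median of -0.24 (adjusted p = 0.562 with an estimated correlation). None of the 115 passed over all genes or adjusted over the list alone. With the batch term 60 of 115 lay above 0 and the list was not called, with a camera adjusted p of 0.848, a median of 0.02 and a test pointing lower. KCNJ1 was then the 1 member that fell. The 0 ppb libraries of batch 4 lay below the other provider libraries by a median of -0.23 over this list. The sodium-potassium ATPase list was not called in either fit, with camera adjusted p of 0.194 and 0.245 and 11 and 9 of its 16 measured members above 0. The metal response list, 12 measured members that include hsp70l, had a camera adjusted p of 0.203 with the site term. It was called higher with the batch term at 0.0291 (adjusted p = 0.479 with an estimated correlation), with 8 of 12 above 0. In both fits hsp70l was the 1 member past the test over all genes, and the metallothionein MT1X was not among the 12.

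**Figure D3:**
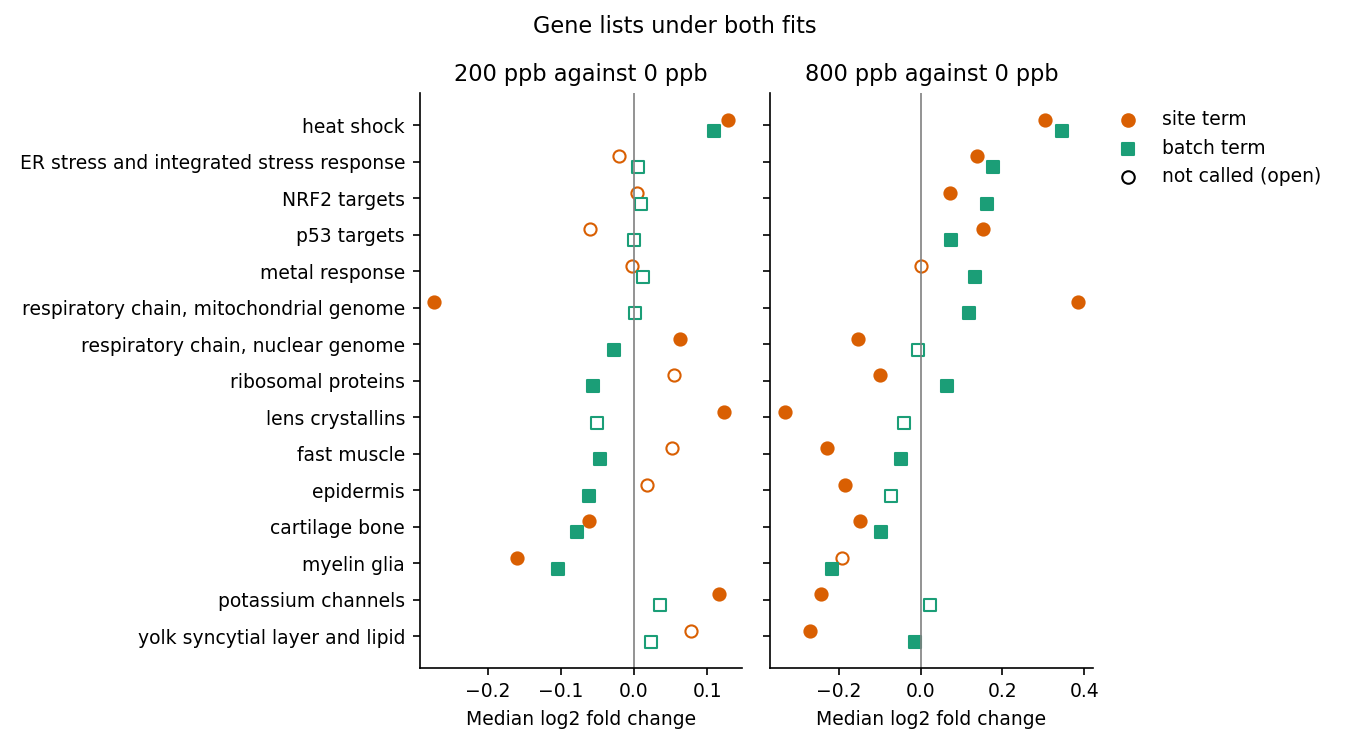
Median log2 fold change of 15 gene lists at 200 ppb and at 800 ppb against 0 ppb; circles are fits with the site term, squares fits with the library batch term, and filled symbols are lists called by camera at the preset correlation. The heat shock list lies at 0.30 and 0.34 at 800 ppb, while lens crystallins lie at -0.33 with the site term and -0.04 with the batch term.

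The comparison of 200 ppb with 0 ppb asked whether the lower dose also changed transcripts. No gene passed the test. HSP90AA1, with the smallest p, was at 91.0 and 119 CPM in 0 and 200 ppb replicate 2, 58.1 and 81.4 CPM in replicate 1, and 125 and 168 CPM in replicate 3, a 1.44-fold difference over the groups (log2 fold change 0.52, SE 0.16, n = 5 and 3). hsp70.3 was 14.5 ± 7.14 CPM (SD, n = 5) at 0 ppb and 22.5 ± 11.2 CPM (SD, n = 3) at 200 ppb, and the HSPA8 gene ENSDARG00000037403 2.88 ± 0.826 and 4.101 ± 1.58 CPM. Among 20867 genes edgeR's quasi-likelihood test called 0, with 120 at an unadjusted p under 0.05 (61 higher and 59 lower). DESeq2 and limma-voom called 0 each. The 120 are fewer than a share of 0.05 of the genes, so the test was conservative. Of 56 groupings of the 0 and 200 ppb libraries, the real one among them, 51 gave as many. The absence of called genes is therefore weak evidence that 200 ppb changed nothing. The smallest p values after HSP90AA1 belonged to dnah9, a dynein of motile cilia, with a log2 fold change of 1.37 (SE 0.43), the unnamed genes si:ch211-131k2.2 with -3.06 (SE 0.98) and si:ch211-213d14.3 with -1.45 (SE 0.47), and ABHD8 with 1.12 (SE 0.37). Levels were low: at 0 and 200 ppb dnah9 averaged 0.545 and 1.51 CPM, and si:ch211-131k2.2 0.560 and 0.0637 CPM. In 0 ppb replicates 4 and 5, of batch 4, si:ch211-131k2.2 was at 1.27 and 0.906 CPM, against 0.187 to 0.238 CPM in the other 0 ppb libraries. Batch 4 holds no 200 ppb library, and with the batch term the log2 fold change of si:ch211-131k2.2 was -2.14 (SE 0.93).

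Replicate numbers paired the 0 and 200 ppb libraries, and the paired fits moved the count. These pairs are also batches 1, 2 and 3, so the replicate block and the batch term are not separate support at 200 ppb. With the replicate block and the 0 and 200 ppb libraries only, 2 genes passed edgeR's test with Benjamini-Hochberg adjustment: HSP90AA1 rose by 0.44 on the log2 scale (SE 0.05, adjusted p = 8.44e-05) and hsp90aa1.1, another HSP90 gene, by 0.35 (SE 0.06, adjusted p = 0.0185), both higher in 3 of 3 pairs. With the replicate block and the site term over all 10 libraries 6 genes passed, with the chaperone hsp70.3 higher by 0.47 (SE 0.08), the metallothionein MT1X higher by 0.53 (SE 0.09), the globin gene HBE1 lower by -0.30 (SE 0.06) and the unnamed ENSDARG00000116076 added to both HSP90 genes. Dropping the site term from that block left 0, and with the library batch as a term 0 passed with 230 at an unadjusted p under 0.05. The 230 are also fewer than a share of 0.05 of the genes.

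Of the 48 lists 9 were called at 200 ppb, 4 higher and 5 lower, and none held after adjustment with an estimated correlation. The heat shock list was higher, 16 of 23 above 0 with a median of 0.13 and a camera adjusted p of 0.00208 (adjusted p = 0.265 with an estimated correlation). The estimate for this list was -0.0179, below the preset 0.01, so correlated members do not account for its lost call. With the library batch as a term 20 of 23 lay above 0 with a median of 0.11, and adjusted over the list alone 1 member passed, hsp90aa1.1, against 0 over all genes. The myelin and glia list was lower, 3 of 20 above 0 with a median of -0.16 (adjusted p = 0.568 with an estimated correlation); the Notch target her4.2 had a log2 fold change of -0.37 (SE 0.15) and GFAP, an intermediate filament of glia, -0.15 (SE 0.09). Potassium channels were higher, 77 of 115 above 0 with a median of 0.12, with kcnd1 at 0.42 (SE 0.19) and KCNA1 at 0.44 (SE 0.22), and the call was absent with the batch term at an adjusted p of 0.302. Lens crystallins (36 of 43 above 0) and nuclear-encoded respiratory chain genes (85 of 107) were higher, and mitochondrial-genome respiratory chain genes (1 of 13 above 0), immediate early genes (3 of 25), cartilage and bone (7 of 30) and photoreceptors (6 of 32) were lower. These 6 and the potassium channels ended at adjusted p = 0.894 with an estimated correlation, and no member of the 9 lists passed over all genes or adjusted over the list alone with the site term. Lens crystallins turned with the batch term, 17 of 43 above 0 and not called. The nuclear respiratory chain was then called lower, 40 of 107 above 0 (camera adjusted p 0.0465, adjusted p = 0.998 with an estimated correlation). Ribosomal proteins were then called lower, 14 of 93 above 0 (camera adjusted p 5.58e-10, adjusted p = 0.998 with an estimated correlation), as were epidermis, fast muscle and the neutrophil and macrophage list (adjusted p = 0.998, 0.898 and 0.998 with an estimated correlation).

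Under the replicate block over all 10 libraries 4 of the 9 lists kept their call, heat shock higher and cartilage and bone, myelin and glia and photoreceptors lower, each with adjusted p = 0.976 with an estimated correlation. On the 0 and 200 ppb libraries alone the replicate block, chosen after the data were seen, called 10 lists, heat shock higher with a median of 0.11 and 9 lower. Ribosomal proteins were lower with a camera adjusted p of 2.54e-11, epidermis with 5.23e-06, fast muscle with 0.00367, neutrophils and macrophages with 0.00721 and the hatching gland with 0.0244, none of them called with the site term. The nuclear respiratory chain was called lower at 0.0295, against higher with the site term. None of the 10 held: adjusted p = 0.665 with an estimated correlation for heat shock and for cartilage and bone, whose unadjusted p were 0.0277 and 0.0214, 0.938 for ribosomal proteins, 0.998 for the nuclear respiratory chain and 0.834 for the other 6.

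The comparison of 800 ppb with 200 ppb asked what separated both exposed groups. HSP90AA1 was 123 ± 43.4 CPM (SD, n = 3) at 200 ppb and 359 ± 66.0 CPM (SD, n = 2) at 800 ppb, with a log2 fold change of 1.33 (SE 0.21), SLC7A3 differed by 1.01 (SE 0.14), SLC1A4 by 1.23 (SE 0.20), the arrestin-domain gene ARRDC3 by 1.08 (SE 0.18) and apoa4a by -1.10 (SE 0.16). None passed: edgeR called 0 genes, with 1852 at an unadjusted p under 0.05 and a smallest adjusted p of 0.298, while limma-voom called 0 and DESeq2 34. No batch held both doses. With the library batch as a term, which joins 800 and 200 ppb through the 0 ppb libraries of each batch, 16 genes changed, 9 higher and 7 lower. HSP90AA1 rose 2.96-fold (1.57, SE 0.14), the lysosomal protease gene ctsla 2.48-fold (1.31, SE 0.13), MT1X 2.59-fold (1.37, SE 0.23), the mitochondrial protease gene LONP1 1.73-fold (0.79, SE 0.12) and PHGDH 1.89-fold (0.92, SE 0.15), while selenop fell by 0.62 (SE 0.09) and PC by 0.71 (SE 0.11). That count became 2 when any library of batches 1 to 3 was left out, 7 without 800 ppb replicate 1 and 56 without 800 ppb replicate 2.

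Of the lists 12 were called between 800 and 200 ppb, 4 higher and 8 lower, and 0 held after adjustment with an estimated correlation. Heat shock was higher, 18 of 23 above 0 with a median of 0.34 (adjusted p = 0.0847 with an estimated correlation), with 0 members past the test over all genes and 4 adjusted over the list alone; hsp70l had a log2 fold change of 1.75 (SE 0.31). The endoplasmic reticulum stress and integrated stress response list was higher, 31 of 47 above 0, with 15 members adjusted over the list alone and 0 over all genes (adjusted p = 0.722 with an estimated correlation). Mitochondrial-genome respiratory chain genes (12 of 13 above 0) and p53 targets (19 of 28) were higher. Lens crystallins (7 of 43 above 0), nuclear-encoded respiratory chain genes (17 of 107), fast muscle (1 of 25), potassium channels (33 of 115), yolk syncytial and lipid genes (6 of 22), epidermis (9 of 38), ribosomal proteins (26 of 93) and liver (9 of 37) were lower. Together these 10 lists ended at adjusted p = 0.722 with an estimated correlation. Adjusted over the list alone 1 lens crystallin and 3 yolk syncytial and lipid genes were lower, with DGAT2, which makes triglycerides, at -1.45 (SE 0.32). Ribosomal proteins were called higher with the batch term, 87 of 93 above 0 (camera adjusted p 5.69e-13, adjusted p = 0.921 with an estimated correlation). The nuclear respiratory chain turned to a median of 0.02 and was not called. The calls of lens crystallins, fast muscle, potassium channels, epidermis and liver also ended, with medians of -0.05, -0.01, -0.03, -0.01 and -0.06.

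No gene was called in both comparisons against 0 ppb with either term, since 200 ppb had no called gene, and independent lists would share 0 in each direction. Across the 20867 genes, which are not independent replicates, the effects of both doses correlated at r = -0.206 with a covariance of -0.0252. Unchanged groups simulated against the same 0 ppb libraries gave r = 0.271 ± 0.0114 (SD over 20 simulations) and a covariance of 0.0329, so the observed covariance differed by -0.0581. The simulation keeps the shared 0 ppb libraries but not the batches, which separate the 200 ppb from the 800 ppb libraries, so this difference and its SD do not account for them. With the library batch as a term, where the effects of both doses come from different libraries, r was 0.0317. Splitting the provider's 0 ppb libraries between the comparisons gave r = 0.012 where each dose was set against 0 ppb libraries of its own batches. It was -0.662 where 200 ppb was set against 0 ppb replicates 4 and 5 of batch 4, and 800 ppb against replicates 2 and 3. Splits that mixed the batches lay between. The effect of 200 ppb differed between the library sites in 0 genes by edgeR's interaction test with Benjamini-Hochberg adjustment, with 9 genes at an unadjusted p under 0.05, the hospital core holding 1 library at each dose. The 9 are far fewer than a share of 0.05 of the genes, so this result is weak evidence of equal effects at both sites.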

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

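The tests chosen only after their result was seen are those of the library batch, the thallium dose, the spread between batches and the sign changes; the test of library size and the counts of other splits were set before. Among 84 values tested in the 5 libraries at 0 ppb, 5 had a library far from the other 4, with a gap over 0.71 of the whole range, where chance gives about 1 in 20. Replicate 1 held a total of 48.3 against 12.3 to 16.5 in the others, in megareads (ratio 0.882). The crystallin crygm2d11 was at 19.7 CPM in replicate 1 against 53.4 to 67.0 CPM (0.713), and crygm2f at 1.96 CPM in replicate 3 against 0 to 0.528 CPM (0.730). Replicate 1 also stood apart for mt-nd4l of the mitochondrial genome, 471 CPM against 126 to 196 CPM (0.799). The p53 target DDB2 was at 17.7 CPM in replicate 5 against 9.46 to 11.6 CPM (0.735). For the total and for crygm2f the 200 ppb library of the same batch was also high. It was 32.2 megareads in 200 ppb replicate 1, and 2.65 CPM in 200 ppb replicate 3. The batch partners for the other flagged values are not given here.

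Heat shock genes were higher at 800 ppb. With the library batch as a term their median log2 fold change was 0.345 (adjusted p = 0.0215 with an estimated correlation), against 0.30 with the site term, which argues against batch as the whole cause. Thinning every library to the total of the smallest left a median of 0.31 (adjusted p = 0.00673 with an estimated correlation), which argues against library size. At 200 ppb, in libraries that do not enter the batch-term effect of 800 ppb, the median was 0.109, with an unadjusted p of 0.00728 with an estimated correlation by limma's camera and 0.349 after adjustment over the lists; with the replicate block over all libraries the unadjusted p was 0.101. A response of chaperone genes to thallium may therefore underlie the pattern, a hypothesis found and tested on the same libraries, and the structure inside batch 4 stays open as a contribution.

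Lens crystallin, fast muscle and nuclear-encoded respiratory chain genes were lower at 800 ppb with the site term, by a median of -0.19 over 175 genes. The 0 ppb libraries of the batch that holds the 800 ppb libraries were lower than the provider's other 0 ppb libraries by a median of -0.30, and with the batch as a term the median was -0.0186. A candidate explanation is thus the library batch, in which embryo stage, handling or counting could differ, none of them tested. Whether thallium adds to it cannot be told apart from no effect here, since the median of -0.0186 lies near 0 and the smallest p of the 3 lists with an estimated correlation was 0.205.

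At 800 ppb 9 genes passed with the site term and 65 with the batch term. Over the 65 genes the standard errors were 1.42 times as large with the site term (median), while the log2 fold changes were 0.931 times as large. The 65 genes were chosen by the batch fit, which favours a larger ratio. Over all genes, which that fit did not choose, the ratio was 1.2. The common dispersion was 0.0419 with the site term and 0.00757 with the batch term. The ratio over all genes and the dispersions argue against that choice as the whole cause of the larger standard errors. Whether differences between batches counted as spread account for the 65 calls cannot be told, since the 1.2 over all genes is below 1.42. How much of the 1.42 came from the choice of genes cannot be told. Of the 65 genes 5 changed sign, FABP1, zgc:158463 and 3 genes without a name, but both fits hold the same 800 ppb and batch 4 libraries, so whether genes are set by the batch stays open. With 2 libraries against 2 inside batch 4, a further grouping of the same libraries stays open, as the splits show.

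Other splits of the libraries gave the following. At 200 ppb the real split called 0 genes, so 56 of 56 splits were as large by construction and the count says nothing about chance; the highest other split called 2, and of the 8 splits that part 3 pairs as the real one does the highest other called 0. At 800 ppb with the site term 1 of 21 splits, the real one with 9 genes, was as large and the highest other called 1. By the number of genes at an unadjusted p under 0.05, 993 in the real split, 8 of the 21 were as large. These splits exchange libraries across batches, so whether chance can be excluded within a batch stays open. Inside batch 4 there are 3 splits, too few for a share under 0.05; the real one gave 65 genes and 2 of the 3 were as large. The split of 0 ppb replicate 4 and 800 ppb replicate 1 from 0 ppb replicate 5 and 800 ppb replicate 2 gave 439, which points to a structure of these libraries, and with 5 pairs of libraries as a term, chosen from this split and not from the labels, 274 genes changed at 800 ppb against 0 ppb.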

How the results depend on the processing

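Fits with the library batch, the recovered reads, the 5 pairs of libraries, the replicate block on 0 and 200 ppb only, and every alternative to the batch-term counts were chosen after the data were seen; the others were planned. Unless a cause is named, the cause was not tested. For genes changed at 200 ppb against 0 ppb, the count of 0 became 6 with the replicate block and site term, 2 with the block on 0 and 200 ppb libraries, 1 with 5 pairs of libraries and 8 for the batch term with no filter, and stayed 0 in every other fit, each library left out included.

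For genes changed at 800 ppb against 0 ppb, the 9 became 0 without the site term, 1 with the provider's libraries alone, 1 with the 2 groups alone, 1 at an adjusted p under 0.01 (a stricter threshold by construction), 42 with DESeq2, 2 with limma-voom, 5 with upper-quartile factors, 15 with recovered reads, 65 with the batch term, 75 with both, and 274 with 5 pairs of libraries. Leaving out 1 library gave 0 to 9. The direction of 9 of 9 genes held under each setting run for single genes, all of which reuse libraries that chose these genes. For genes changed at 800 ppb against 0 ppb, library batch term, the 65 became 98 with DESeq2, 98 with limma-voom, 216 with no filter and 274 with 5 pairs, and 33 to 114 with a library left out. At 800 ppb against 200 ppb the 0 became 10 with the 2 groups alone, 34 with DESeq2, 16 with the batch term, 15 with recovered reads and the batch term, and 115 with 5 pairs. The 16 of the batch term became 30 with DESeq2, 101 with no filter, 10 with robust dispersion and 115 with 5 pairs, and 2 to 56 with a library left out.

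The 800 ppb libraries lie in another batch than the libraries of 0 and 200 ppb with the same number. With the replicate block 675 genes were called at 800 ppb against 0 ppb and 1140 against 200 ppb, and with the site term added 6590 and 6744; by construction these fits set 800 ppb libraries of batch 4 against libraries of batches 1 to 3 with the same number. Inside batch 4 the deviations of 0 ppb replicate 4 and 800 ppb replicate 1 correlated at 0.216, and those of 0 ppb replicate 5 and 800 ppb replicate 2 at 0.00747. The deviations of both 800 ppb libraries mirror each other, so these values can hardly show pairs. The 5 pairs, which the labels do not give, join these libraries.

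Lists called went from 9 at 200 ppb against 0 ppb to 4 with the replicate block and 0 with an estimated correlation and with fry; from 16 at 800 ppb to 8 without the site term, 1 with an estimated correlation and 1 with fry; and from 12 at 800 against 200 ppb to 0 with an estimated correlation and 1 with fry. Leaving out a library gave 8 to 14 lists at 200 ppb (14 without 200 ppb replicate 3) and 9 to 19 at 800 against 200 ppb (19 without 200 ppb replicate 3).

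Lists whose test turned, whatever the sign of their median, had these medians at 200 ppb against 0 ppb: without the site term, 0.0117 for lens crystallins and -0.0231 for the nuclear respiratory chain; with the replicate block -0.0419, -0.0147 and, for the mitochondrial genome, 0.00153; with the batch term -0.0513 for lens crystallins and -0.0280 for the nuclear respiratory chain. Leaving out 200 ppb replicate 2 turned the mitochondrial-genome list to 0.0116 and photoreceptors to 0.0384, where leaving out 200 ppb replicate 3 gave the lowest values, -0.514 and -0.389. At 800 ppb against 0 ppb the medians of lens crystallins, nuclear respiratory chain and ribosomal proteins were -0.0859, 0.0506 and 0.0758 without the site term, and 0.546, 0.426 and 0.495 with the replicate block, where yolk syncytial and lipid genes had -0.0450; with the batch term the nuclear respiratory chain was -0.00584 and ribosomal proteins 0.0654. At 800 against 200 ppb the same 3 lists had -0.123, 0.0365 and 0.158 without the site term and 0.582, 0.459 and 0.553 with the replicate block, and with the batch term 0.0154 for the nuclear respiratory chain and 0.124 for ribosomal proteins. Under the replicate block and site term ENSDARG00000116076 reversed to 0.39 at 200 ppb and RPS28 to -0.33 at 800 ppb, where the effect rests on 800 ppb replicate 2 alone.

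The correlation of the 200 ppb and 800 ppb effects, -0.206, was -0.348 without the site term, -0.295 with the stricter filter, 0.186 with no filter and 0.0317 with the batch term, and -0.209 to -0.0775 with a library left out. With the 0 ppb libraries split it was 0.012, -0.662, -0.354, -0.425, -0.343 and -0.459. The value of 0.012 set each dose against its own batches, -0.662 exchanged the batches, and the others mixed them. Other scalings shifted the median of all genes by at most 0.0178 in the comparisons with 0 ppb. Thinning each library to the smallest total left 8 genes with the site term and 62 with the batch term at 800 ppb.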

Other observations

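The tests of the 65 genes at 200 ppb and all fits with the batch term were chosen after the results were seen; list tests with the site term were planned. Of the 65 genes changed at 800 ppb with the batch term, 50 (76.9%) had the same sign at 200 ppb in the libraries of batches 1 to 3, against 52.4% of all genes, 40 of them higher and 10 lower. Across these genes the effects correlated at r = 0.557, against 0.0317 over all genes, and the median ratio of the 200 ppb to the 800 ppb effect was 0.0898. In the separate pairs 53, 40 and 45 of the 65 genes went the same way, against 54.3%, 49.1% and 52.1% of all genes. The metallothionein MT1X was 31.1 ± 28.4 CPM (SD, n = 3) at 200 ppb against 21.0 ± 11.3 CPM (SD, n = 5) at 0 ppb, and dnajb1b 18.02 ± 6.25 against 15.0 ± 3.34 CPM. These SDs hold the differences between batches. With the replicate block and site term MT1X was higher by 0.53 on the log2 scale (SE 0.09), while 0 genes passed at 200 ppb with the batch term. That effect of MT1X rests on the pairs of batches 1 to 3 alone. The 65 genes were chosen for their 800 ppb effect, and genes are not independent replicates.

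With the batch term the cell cycle list was lower at 800 ppb, 16 of 59 measured members above 0 (adjusted p = 0.763 with an estimated correlation), with the replication genes MCM5 at -0.26 (SE 0.08) and MCM7 at -0.27 (SE 0.09). NRF2 targets were higher, 21 of 27 above 0 (adjusted p = 0.236 with an estimated correlation), with 0 members past the test over all genes and 3 adjusted over the list alone; GCLC and GCLM, which make glutathione, had log2 fold changes of 0.39 (SE 0.10) and 0.54 (SE 0.14). The estimated correlation of the NRF2 list was -0.00802, below the preset 0.01, so correlated members do not account for its lost call. Hypoxia targets were higher as a list, 15 of 22 above 0 (adjusted p = 0.763 with an estimated correlation), with 1 member past the test over all genes and 2 adjusted over the list alone. Myelin and glia genes were lower, 4 of 20 above 0 (adjusted p = 0.506 with an estimated correlation). The lists of cardiomyocytes, neurons, erythroid cells, hair cells, ionocytes and pronephros were not called at 800 ppb in either fit.

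Some transcripts were higher in batch 4 than in the other batches. The unnamed gene ENSDARG00000116076 averaged 438 CPM in the 0 ppb libraries of batch 4 and 279 ± 57.7 CPM (SD, n = 2) at 800 ppb, against 25.7 ± 9.50 CPM (SD, n = 3) at 200 ppb, and zgc:158463 averaged 363 CPM in the same 0 ppb libraries and 21.5 ± 18.5 CPM (SD, n = 3) at 200 ppb.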
